A study of Homo sapiens with 2 samples.

How the data were processed

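The series holds 2 single-cell RNA sequencing libraries of day-21 human collecting duct organoids, 1 from starting cells cultured for 2 weeks and 1 from starting cells cultured for 6 weeks, and groups were taken from the sample titles. Per the labels' protocols, organoids were freed from Matrigel on ice with a recovery solution, dissociated with Accutase and loaded on the 10x 3' chemistry. The values are UMI counts per gene and cell barcode, deposited by the authors without normalization; per the file headers and the submitters' processing notes they were made with Cell Ranger 7.0.1 on the hg38 build. The cell calling settings and the annotation release were not given in the sources used here. Both matrices listed the same 36601 genes, and the libraries shared 1 barcode sequence. The deposited counts carry UMIs, so amplification copies were already merged.

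Cells were kept with at least 1000 genes and at most 20% mitochondrially encoded UMIs. This left out 863 barcodes of the 2-week library (670 under the gene minimum, 628 over the mitochondrial limit, 435 both) and 678 of the 6-week library (562, 437 and 321). The kept cells held 97.7% and 98.4% of UMIs, with median mitochondrial shares of 8.14% and 6.57% and ribosomal protein shares of 14.1% and 15.0%. Scrublet, a doublet caller run through scanpy, marked 0 of 3515 and 3 of 3014 cells (0.0995%) and so did not work here, and no cell was removed by it. Free RNA was not subtracted.

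UMIs were summed per library over all kept cells, or per cluster, and divided by the summed total to give CPM. Poisson intervals of CPM, conditional binomial intervals of ratios and Clopper-Pearson intervals of shares were exact, at 95%, and 0 counts were set against a floor of 3 counts. Genes with a mean of at least 5 CPM in the cells compared were used over all cells and within clusters, for single genes, lists and the genes 2-fold apart over all cells. Counts of all 2-fold genes within the urothelium-like clusters took those with at least 20 CPM, and a ratio of at least 2 either way was counted. No test between libraries was run, since each culture time had 1 library, and genes and cells were not treated as replicates. On simulated counts for 12361 genes, all 50 genes changed 3-fold, all 50 changed 4-fold and all 46 set to a ratio of 0.25 passed the 2-fold threshold, against 0 of 50 changed 1.5-fold and 0 of 12165 unchanged genes. Both simulated libraries were Poisson draws from 1 shared profile. This checks counting error only and gives no rate of false calls between real libraries. The 95% intervals covered the simulated ratio for 90.9% of the unchanged genes and for 88.0% to 96.0% of each changed set.

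Lists of 708 gene symbols in 46 groups were fixed before the data were examined, and 2 symbols were absent from the gene names in the matrices. A list with at least 5 measured members was summarised by its median log2 ratio, the percentile of that median among 10000 random lists of equal size drawn from the same 10 expression bins, and a counting interval from Poisson resampling. Shares of cells with a UMI were taken after each cell was thinned to 3000 UMIs, which left out 148 cells of the 2-week and 125 cells of the 6-week library.

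Cells of both libraries were clustered together without integration on log-normalised UMIs (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.6), which gave clusters numbered 1 to 10. The clustering was repeated without the genes that differed 2-fold between the libraries, and these clusters are lettered A to J. Shares were compared in the lettered clusters, and the shares of the urothelium-like class of the numbered clusters are given beside them. A cluster was named after the marker list with the most members at least 2-fold above the other cells (5 CPM added, found in at least 25% of its cells), where there were at least 3, more than for any other list apart from cycling genes, and at least 1 among its top 10 genes. The markers were fixed in advance and this scoring was chosen after seeing the data.

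Genes were named by a fixed rule. It took the 12 highest and 12 lowest ratios among genes with a mean of at least 20 CPM, the 6 highest and 6 lowest in a named class with a mean of at least 50 CPM, and a set of collecting duct, ureteric bud, cystic disease and cycling genes. It also took 4 members of each list (the 2 most abundant and the 2 with the largest ratios) and the 5 leading genes of each cluster. Genes with only a clone name, mitochondrially encoded and ribosomal protein genes were left out. Some genes that the rule names are not reported here. Named beyond the rule, after their values were seen, were the list members UPK1B, FOXJ1, FOXA2, POU5F1 and SOX2 and the nuclear RNA MALAT1. Gene positions came from GENCODE release 29 on GRCh38, the same assembly as hg38, which gave a position for 34616 of the 36601 genes by identifier.

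Alternatives were all deposited barcodes, a stricter cell filter (2000 genes, 10%), totals scaled by edgeR 4.0.16 TMM factors or DESeq2 1.42.0 size factors, totals without mitochondrial and ribosomal protein genes, no CPM minimum with 1 UMI added to each gene, a minimum of 20 CPM, the mean of each cell's own CPM, cycling cells left out, thinned cells, thinning to 1500 UMIs, at least 2 UMIs of a marker, resolutions of 0.3 and 1.0, clustering without cycling genes and each library clustered alone. Alternatives chosen after seeing the data were the 5% of cells with the most UMIs left out, the endoderm-like cluster left out, clusters 1, 4, 5, 6 and 7 alone, and comparison within the lettered clusters. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9, and R 4.3.3.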

Results

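Single-cell RNA sequencing was used to profile collecting duct organoids grown from 1231A3, an established human induced pluripotent stem cell line, and taken on day 21. The organoids had been rebuilt from cells that the labels call UBTCs, which had been kept in culture for 2 or 6 weeks beforehand, and each culture time gave 1 library. The 2-week library held 79317975 UMIs (unique molecular identifiers, 1 per captured transcript) in 4378 barcodes, and the 6-week library 79903511 UMIs in 3692 barcodes. After quality filtering, 3515 cells (80.3%) with a median of 15703 UMIs and 5094 genes remained in the 2-week library, and 3014 cells (81.6%) with a median of 18865 UMIs and 5438.5 genes in the 6-week library. Levels are in CPM, UMIs scaled to the summed total of the library, and 1 CPM corresponded to 77.5 UMIs in the 2-week and 78.6 UMIs in the 6-week library. With 1 library per culture time there is no replicate check, no p-value is given, and every interval is a 95% interval that covers counting error only.

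The first question was which cell types the organoids held and whether the culture time of the starting cells went with a different make-up. Most cells of both libraries were renal epithelium that expressed PAX8 and GATA3, transcription factors of the ureteric lineage, and AQP2, the vasopressin-regulated water channel of collecting duct principal cells. Urothelium-like cells, which expressed the uroplakin genes UPK1B, UPK2 and UPK3A of bladder and ureter lining, made up 17.6% (16.3 to 19.03) of the 6-week library and 5.06% (4.36 to 5.84) of the 2-week library. A group led by SST, which encodes somatostatin, and by the protease gene MMP7 and the mucin gene MUC5B made up 12.4% (11.3 to 13.7) of the 6-week and 4.64% (3.97 to 5.39) of the 2-week library. AQP2-rich cells with TPSB2 and LEFTY1, a Nodal antagonist, among their leading genes were the counterpart: 2 such clusters held 18.8% and 18.1% of the 2-week library but 5.74% and 5.81% of the 6-week library. Multiciliated-like cells (59 of 3014) and endoderm-like cells (38 of 3014) were found almost only or only in the 6-week library.

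These shares came from a clustering that left out the genes differing at least 2-fold between the libraries, and its 10 clusters are lettered A to J by size. Clusters A to D were the AQP2-rich epithelium, with 949 CPM of AQP2 in A, 699 CPM in B, 939 CPM in C and 676 CPM in D. Cluster A, led by PNOC and AQP3, held 18.0% (16.7 to 19.3) of 2-week and 20.7% (19.2 to 22.2) of 6-week cells, and cluster B, led by PTH2R and CNTN5, held 18.5% (17.2 to 19.8) and 19.2% (17.8 to 20.6). The near-equal shares of B depended on the clustering: on all variable genes cluster 4, also led by PTH2R and CNTN5, held 6.34% and 18.9%, and a class named principal cell-like held 15.4% and 38.3% at resolution 0.3 and 4.52% and 18.1% at resolution 1.0. On all variable genes, cluster 5, led by DCLK1 and ZIC2, held 22.0% of the 2-week but 0.299% of the 6-week library. Without the 2-fold genes, nearly all its cells were spread over A to D (125, 393, 130 and 125 cells), so the shares of A to D do not show this difference. Cluster C was led by TPSB2, NPPC, CD52 and LEFTY1 and held 662 2-week cells and 173 6-week cells. Cluster D was led by TPSB2 and LEFTY1 and held 635 and 175 cells. TPSB2 shares sequence with other tryptase genes, so its level is uncertain. Cluster G, the SST and MUC5B cluster, had 419 CPM of AQP2, whereas the urothelium-like cluster F had 10.9 CPM.

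Clusters E and H stood apart by RNA content as well as by genes. Cluster E, led by EPHA6, had 167 CPM of AQP2, a median of 8833 UMIs and 0.622% ribosomal protein UMIs, and held 14.7% of the 2-week and 9.69% of the 6-week library. Cluster H, led by RUNX2, had 16.9 CPM of AQP2, a median of 7586.5 UMIs and 0.926% ribosomal protein UMIs, and held 2.22% and 5.64%. The nuclear RNA MALAT1 stood at 29586 CPM in cluster E and 41699 CPM in cluster H. Neither cluster met the naming rule, and neither is called a cell type here.

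**Figure D1:**
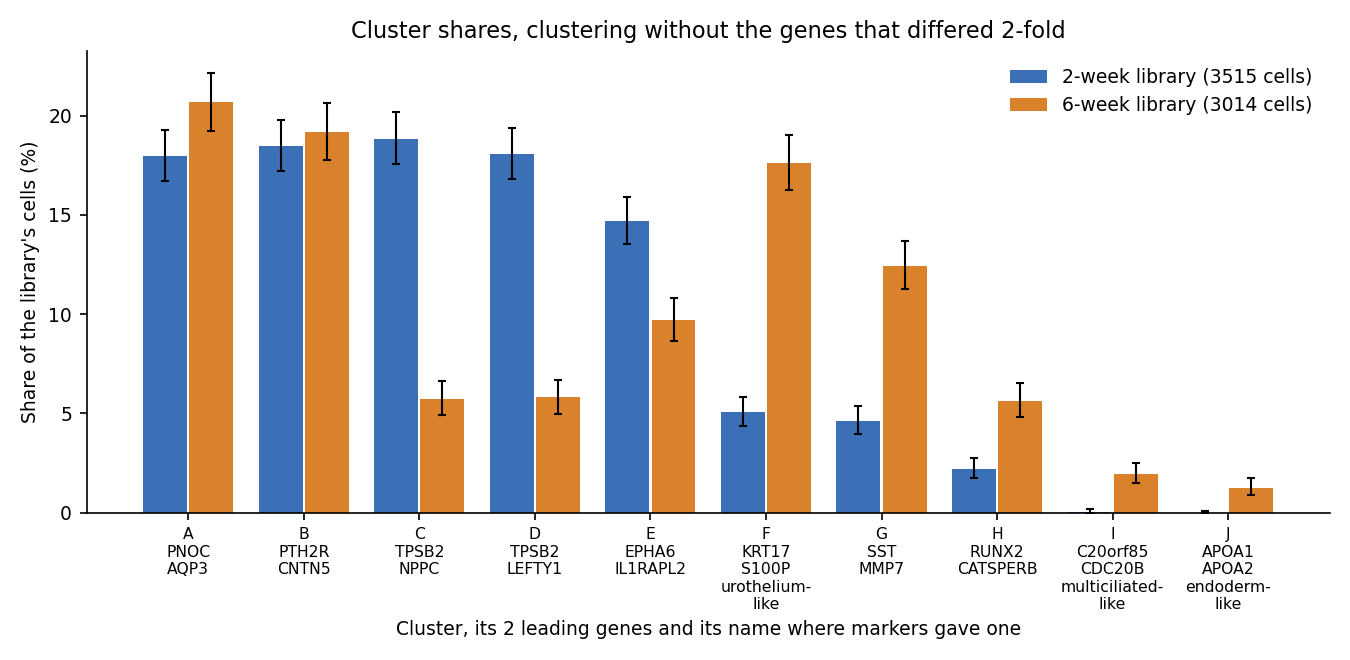
Share of each library's cells (%, bars) in the 10 clusters of the clustering made without the 2-fold genes, with exact 95% binomial intervals for 3515 2-week and 3014 6-week cells; each cluster is marked with its 2 leading genes. Clusters C and D took a larger share of the 2-week library, and F (17.6% against 5.06%) and G (12.4% against 4.64%) a larger share of the 6-week library.

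The urothelium-like name of cluster F rested on 8 of the fixed urothelium markers at least 2-fold above the other cells, and KRT17, S100P, GDF15 and RARRES1 led it. The multiciliated-like cluster I carried 11 multiciliated markers. In it C20orf85 stood at 1179 CPM, the tubulin-binding gene TPPP3 at 439 CPM, and FOXJ1, the regulator of motile cilia, at 170 CPM. It also carried 11 cycling and 5 urothelium markers and had a median of 38653 UMIs, the highest of the 10 clusters, and doublets were not removed. Its 2-week share was 2 of 3515 cells, or 0.0569% (0.00689 to 0.205), and its 6-week share was 1.96% (1.49 to 2.52).

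The endoderm-like cluster J expressed genes of liver and gut. APOA2, an apolipoprotein gene, stood at 6783 CPM in it, TTR, the gene of the carrier protein transthyretin, at 6496 CPM, AFP at 1144 CPM, and the endoderm factor FOXA2 at 82.8 CPM. It had 10.6 CPM of PAX8 and 20.3 CPM of GATA3, and 12 cycling markers were at least 2-fold above the other cells, with MKI67 at 34.1 CPM. It held 1.26% (0.894 to 1.73) of the 6-week library and 0 of 3515 cells of the 2-week library, where the interval allows a share of up to 0.105%. Clusters I and J came almost wholly from 1 library, so each may mark that library and not a cell type that goes with culture time.

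**Figure D2:**
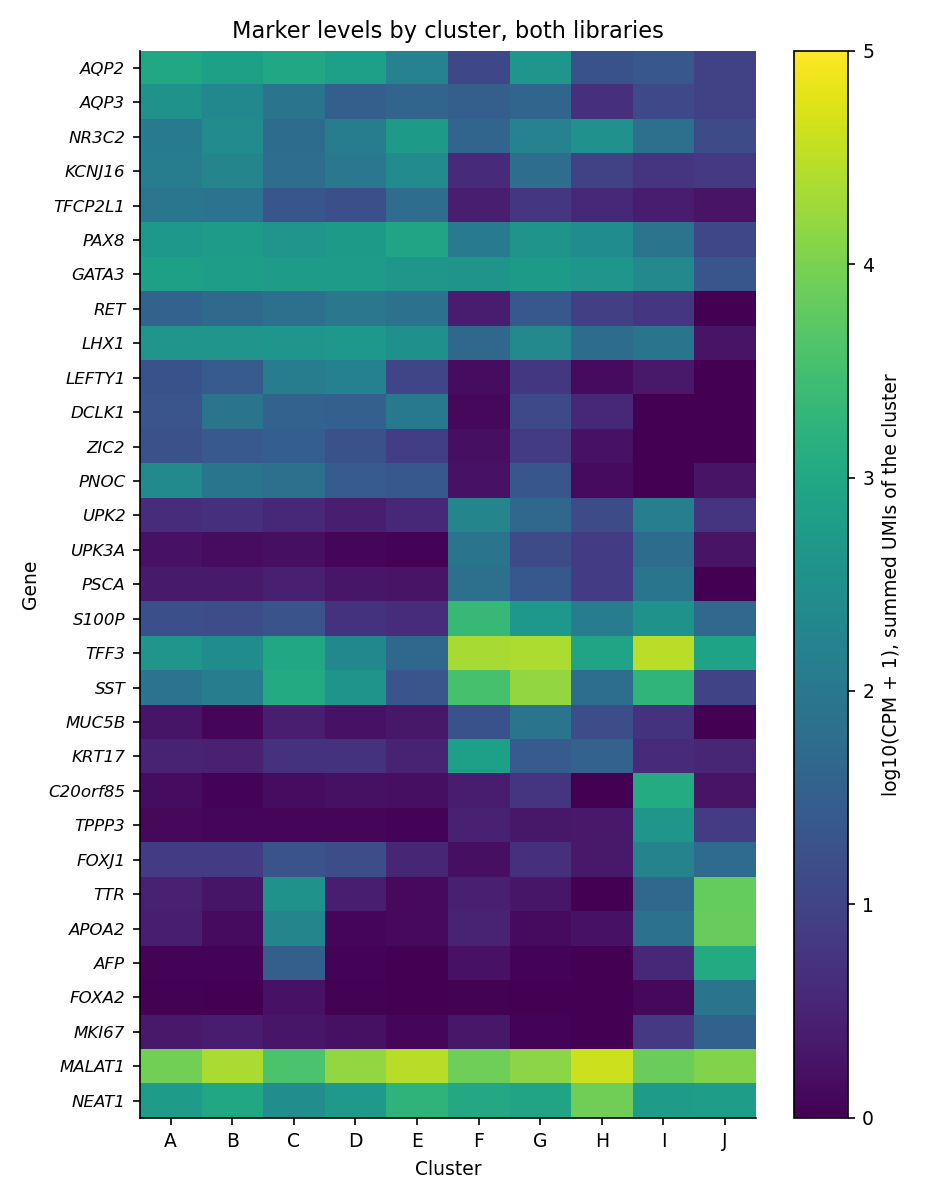
Level of selected marker genes (vertical axis) in clusters A to J (horizontal axis), as log10 of CPM plus 1 from UMIs summed over both libraries. AQP2 is high in A to D (676 to 949 CPM), UPK2 and UPK3A in F and I, SST and MUC5B in G, FOXJ1 and TPPP3 in I, and TTR, APOA2 and AFP in J.

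The second question was which genes differed between the organoids over all cells. The genes highest in the 6-week library against the 2-week library were those of the endoderm-like, multiciliated-like, urothelium-like and SST-led cells, and among those lowest were DCLK1, PNOC and LEFTY1. TFF3, a secreted trefoil peptide of mucous epithelia, stood at 11109 CPM in the 6-week and 942 CPM in the 2-week library (11.8-fold), and SST at 4179 CPM against 496 CPM (8.42-fold). DCLK1, which encodes a microtubule-associated kinase, stood at 77.3 CPM in the 2-week and 2.24 CPM in the 6-week library (34.5-fold lower), and PNOC, the prepronociceptin gene, at 157 CPM and 8.08 CPM (19.5-fold lower). Of 12362 genes with a mean of at least 5 CPM, 356 (2.88%) were at least 2-fold higher and 274 (2.22%) at least 2-fold lower in the 6-week library. AQP2, GATA3 and the epithelial cadherin gene CDH1 had log2 ratios of 0.07, 0.03 and 0.09.

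Among the genes highest in the 6-week library, APOA2 had 2 UMIs in the 2-week library and 156 CPM in the 6-week library, a log2 ratio of 12.56 (10.70 to 15.60). FABP1, a fatty acid binding protein gene, had 3 UMIs and 40.0 CPM (log2 ratio 10.01, 8.46 to 12.29). APOA1 (log2 ratio 9.31), TTR (7.65), SERPINA1 (5.02) and AMBP (3.93), which encode secreted plasma proteins, followed. C20orf85 (5.11) and CDC20B (3.61) were leading genes of the multiciliated-like cluster. S100P stood at 574 CPM against 76.2 CPM (log2 ratio 2.91), and LGALS3, the galectin-3 gene, at 169 CPM against 22.8 CPM (2.89). In GENCODE annotation of the GRCh38 (hg38) build, TFF3 lies on chromosome 21 from 42311667 to 42315651 and SST on chromosome 3 from 187668906 to 187670399.

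The fixed cell type lists differed as well. The urothelium list had a median log2 ratio of 1.82 (1.69 to 1.95) with 7 of 9 members at least 2-fold higher, among them UPK2 (2.04), UPK3A (2.42) and the surface antigen gene PSCA (2.78). In the 2 lettered clusters where this list could be measured its median was 0.28 in F and −0.57 in G, neither above the random range. The gut and lung endoderm list had a median of 5.60 (5.45 to 5.80) over 6 members, which was 2.80 with no CPM minimum and 1 UMI added and 4.42 in thinned cells, and the multiciliated list 0.83 (0.78 to 0.88) over 7. FOXJ1, also of the multiciliated list, was found in fewer 6-week than 2-week cells (1.87% against 3.53% after thinning). The intercalated cell list had a median of 0.74 (percentile 99.8) over 5 members that went both ways, with the ammonia transporter gene RHBG at 1.02 and HEPACAM2 at −2.27. FOXI1, the intercalated cell regulator, stood at 1.30 CPM against 1.10 CPM, and the acid and base transport genes ATP6V1B1, SLC4A1 and SLC26A4 stood at 0.153, 0.140 and 0.471 CPM against 0.0645, 0.0774 and 0.232 CPM. These transport genes rest on few UMIs (12, 11 and 37 against 5, 6 and 18). The log2 ratio intervals of FOXI1, ATP6V1B1 and SLC4A1 spanned 0. The renal epithelium list had a median of 0.02 (percentile 88.8), with ELF3 at 0.94, PAX2 at −0.35 and PAX8 at −0.13.

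Among the genes lowest in the 6-week library were LEFTY1 (87.2 CPM in the 2-week and 5.23 CPM in the 6-week library, log2 ratio −4.06), KLHL29 (−3.90), the POU-domain factor POU3F4 (−3.53), TAFA5 (−2.85) and NKAIN4 (−2.65). SEMA3D, a semaphorin gene, stood at 378 CPM and 64.2 CPM (−2.56, −2.60 to −2.51). BCAT1, which encodes a branched-chain amino acid transaminase, stood at 133 CPM and 22.8 CPM (−2.54). CNTNAP2 (−2.47) and ADARB2 (−2.15) completed the group, together with LIX1-AS1 (−2.29), an antisense gene whose level is uncertain. DCLK1 lies on chromosome 13 from 35768652 to 36131306, and PNOC on chromosome 8 from 28316986 to 28343355.

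The third question was how far collecting duct maturation genes and ureteric tip genes differed. Principal cell genes were higher in the 6-week library: 9 of the 10 measured members of the list had a ratio above 1, and the median log2 ratio was 0.44 (0.39 to 0.47), at percentile 99.99 of 10000 random lists of equal size and expression. AQP3, the basolateral water channel, stood at 215 CPM against 78.9 CPM (2.72-fold), and the sodium channel subunit SCNN1B at 19.5 CPM against 6.96 CPM (2.81-fold). Ureteric tip genes were lower, with a median log2 ratio of −0.86 (−0.99 to −0.68; percentile 0.01) over 7 members, of which 5 were below 0; RET, the GDNF receptor of the branching tip, stood at 25.4 CPM against 67.9 CPM (2.68-fold lower). Within clusters 1, 4, 5, 6 and 7 alone, the AQP2-rich clusters of the clustering on all variable genes, the principal cell median was 0.76 and the tip median −0.28; of these, cluster 5 held 772 2-week and 9 6-week cells.

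Other tip genes were LHX1 (log2 ratio −0.65), CLDN6 (−1.32), WNT11 (−0.37) and SPRY1, which stood at 78.5 CPM against 65.4 CPM. TFCP2L1, a transcription factor of the collecting duct, stood at 66.8 CPM in the 6-week and 23.2 CPM in the 2-week library (log2 ratio 1.53). SCNN1G had a log2 ratio of 0.57 and the mineralocorticoid receptor gene NR3C2 of 0.18, whereas SCNN1A had −0.63. AVPR2, the vasopressin receptor gene, stood at 0.127 and 0.194 CPM, and AQP4 at 0.0891 and 0.142 CPM, with counts too low to show a difference. The stalk list had a median of −0.07 (percentile 45.0, 14 members), with WNT9B at 0.37, GATA3 at 0.03 and CALB1 at −3.08. AQP2 lies on chromosome 12 from 49950741 to 49958881, AQP3 on chromosome 9 from 33441154 to 33447633, and RET on chromosome 10 from 43077027 to 43130351.

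These differences were also present inside the lettered clusters A to G, each of which had at least 100 cells in each library. AQP3 was higher in the 6-week library in 7 of 7 clusters, with log2 ratios from 0.67 to 2.07, and TFCP2L1 in 5 of the 5 clusters where it was measured (1.14 to 2.72). AQP2 was above 0 in 7 of 7, by 0.04 to 0.90 and never 2-fold, with its interval clear of 0 in 6; in cluster A it stood at 1225 CPM against 655 CPM. PTH2R, a parathyroid hormone receptor gene, was higher in 6 of 6 clusters, with 268 CPM against 82.3 CPM in cluster B. RET was lower in 6 of 6 clusters (−1.11 to −0.29), with its interval clear of 0 in 5. The principal cell list had a median above 0 in 7 of 7 clusters, from 0.08 in G to 0.88 in B, and the tip list a median below 0 in 4 of 5. Clusters A to D did not compare like with like. Of their 2-week cells, 19.8% in A, 59.6% in B, 19.6% in C and 19.4% in D came from cluster 5, which held 9 6-week cells. The 6-week cells of B came mostly from cluster 4 (87.9%), which PTH2R also led.

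Most of the 274 lower genes were also lower within clusters. SEMA3D was at least 2-fold lower in 7 of 7 clusters (−3.14 to −1.10), and DCLK1 (−5.72 to −2.60), PNOC (−6.22 to −3.09), KLHL29, LEFTY1 and POU3F4 in 6 of 6. PNOC stood at 472 CPM in the 2-week and 22.0 CPM in the 6-week cells of cluster A, and DCLK1 at 156 CPM and 3.55 CPM in cluster B. Also lower in 7 of 7 clusters were CCND1, the cyclin D1 gene, and CDKN1C, an imprinted cell cycle inhibitor gene. Of the 274 genes, 230 were measured in cluster A and all 230 were lower there, with a median log2 ratio of −1.33, and 264 were measured in cluster B with a median of −1.29; the medians were −0.92 in C and −0.66 in D. Cells of cluster A were mostly from cluster 1 in both libraries (70.8% and 86.7%), but 19.8% of its 2-week cells came from cluster 5. Those of cluster B came mostly from cluster 5 in the 2-week library (59.6%) and cluster 4 in the 6-week library (87.9%). In the clustering on all variable genes the medians were −1.20 in cluster 1, −0.81 in 6, −0.55 in 4 and −0.53 in 7.

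**Figure D3:**
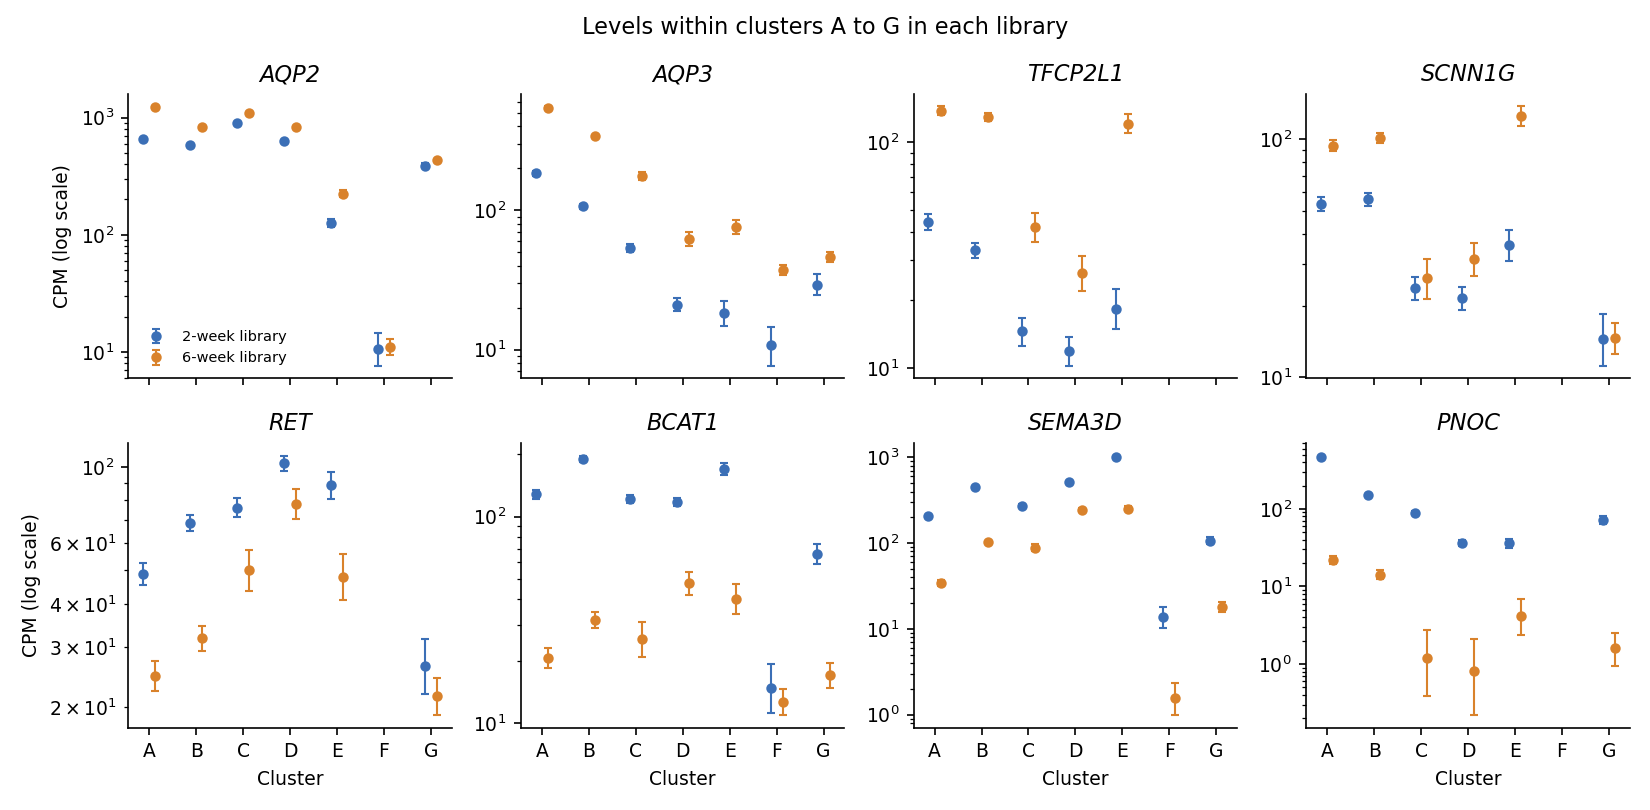
CPM on log axes of 8 genes in the 2-week and 6-week cells of clusters A to G, with 95% Poisson intervals for counting error; a gene is drawn where its mean was at least 5 CPM. AQP3 and TFCP2L1 lie higher in the 6-week cells of every cluster drawn, and SEMA3D and PNOC lower.

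Of the 356 genes higher in the 6-week library, fewer were measured in the AQP2-rich clusters: 156 were measured in cluster A with a median log2 ratio of 0.53, and 50 of them were at least 2-fold higher there. The medians were 0.46 in B, 0.94 in C and 0.71 in D, and 286 were measured in F (0.59) and 298 in G (0.73). In clusters 1, 4, 5, 6 and 7 alone, 112 genes were at least 2-fold higher, of which 41 were among the 356, and 115 of the 356 had the opposite direction. TFF3 was at least 2-fold higher in 7 of 7 lettered clusters (1.25 to 4.69), and SST was higher in 7 of 7 (0.60 to 3.32), but the cells of these clusters differed in origin: 13.9% of the 6-week and 3.47% of the 2-week cells of C came from the SST-led cluster 8, and 24.8% and 12.3% of those of G from cluster 3. In cluster 1 TFF3 was higher (1.01) and SST lower (−1.31). In cluster G, TFF3 stood at 30835 CPM against 5014 CPM and SST at 20305 CPM against 3992 CPM. S100P and LGALS3 were higher in 6 of 6 clusters, and the hypoxia-responsive gene NDRG1 in 7 of 7. S100P stood at 2187 CPM in F and 15.3 CPM in A over both libraries. Free RNA or doublets as its source in other clusters were not tested.

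Shares of cells with at least 1 UMI were compared after each cell was thinned to 3000 UMIs. AQP3 was found in 31.8% (30.1 to 33.5) of 2889 6-week cells and 15.2% (14.0 to 16.5) of 3367 2-week cells, and in 57.6% and 37.5% without thinning. RET was found in 6.40% (5.54 to 7.36) and 16.8% (15.6 to 18.1), unthinned 29.1% and 50.01%. UPK2 was found in 8.65% and 2.08%, unthinned 21.7% and 6.43%. AQP2 was found in 51.8% (49.9 to 53.6) of 6-week and 60.0% (58.3 to 61.6) of 2-week cells, unthinned 66.7% and 78.2%, which goes against its CPM. The mix of cells differed, and AQP2-poor cluster 3 held 22.6% of the 6-week and 3.95% of the 2-week library. Within clusters 1, 4, 6 and 7 the thinned share was higher in the 6-week library (88.1% against 71.1% in cluster 1). In cluster 8 it was lower (45.9% against 49.7%). The order over all cells was therefore not read as a lower share within AQP2-rich cells. As background, the urothelium-like cluster 3, with median depths of 23710 and 19891 UMIs, had thinned shares of 5.83% and 4.38% for AQP2, 10.2% and 2.92% for AQP3, and 0.747% and 2.19% for RET, and cluster 1, with 16003 and 14793 UMIs, had 0.560% and 0.359% for UPK2. For AQP3 this may not be background alone, which was not tested. The urothelium-like cluster F had 31.8 CPM of AQP3 and 10.9 CPM of AQP2, whereas cluster A had 370 CPM and 949 CPM.

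The fourth question was how signalling, stress and metabolic gene groups differed. The WNT response list (median log2 ratio −0.64, −0.72 to −0.54) and the Notch response list (−0.76, −0.83 to −0.66) were lower in the 6-week library than all 10000 random lists, with 7 of 8 and 7 of 10 members below 0; among genes with at least 20 CPM the Notch median was −0.09. The WNT members CCND1 (−1.34), SOX9 (−0.64) and the WNT-amplifying receptor gene LGR5 (−1.64), and the Notch members LFNG (−2.11) and DLL1 (−1.71), a Notch ligand gene, led these; HES1, a main Notch target, stood at 401 CPM against 339 CPM. Hypoxia (0.44), glycolysis (0.47) and cholesterol synthesis (0.28) genes were higher over all cells, as for CA9 (2.28), NDRG1 (0.96), HK2 (24.3 CPM against 9.30 CPM) and GAPDH (0.54). All 22 nuclear-encoded oxidative phosphorylation genes had ratios above 1 (median 0.18, percentile 99.99), whereas the mitochondrially encoded list was lower (−0.29, percentile 0.16).

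Inside clusters A to G the WNT and Notch medians were below 0 in 7 of 7 (−0.94 to −0.23, and −1.31 to −0.02), and so was the NF-kB and chemokine list (−1.11 to −0.38; −0.33 over all cells, percentile 0.135, 12 of 13 members below 0). CXCL8, a neutrophil chemokine gene, had a log2 ratio of −1.64 and NFKBIA stood at 80.3 CPM against 90.8 CPM, while LCN2 of the same list had 2.18. The YAP response list was lower (−0.36, percentile 0.06), with 10 of 10 members below 0. Hypoxia, glycolysis, cholesterol synthesis and interferon response medians did not hold in most clusters: each was above 0 in 3 of 7, and within clusters 1, 4, 5, 6 and 7 alone they were −0.25, −0.13, −0.22 and −0.21. Glycolysis was above the random range in 3 of 7, with its highest median of 0.53 in F, and below it in 1. The interferon list was 0.18 over all cells (percentile 99.4), with B2M at 1.04 and OAS1 at 13.6 CPM against 3.96 CPM. Immediate early genes had a median of 0.42 with 13 of 16 members above 0 and JUNB at 1.14, and were above 0 in 5 of 7 clusters.

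The unfolded protein response list had a median of 0.20 (percentile 99.7), with XBP1, a secretory pathway factor, at 1.08. The p53 and senescence list lay within the random range (0.09, percentile 96.2), although GDF15 (1.60) and the cell cycle inhibitor gene CDKN2A (2.45) were among its 4 members at least 2-fold higher. Heat shock (0.09, percentile 94.7), FGF and GDNF response (−0.16, 8.13), retinoic acid response (−0.10, 27.2) and BMP and TGF-beta response (−0.14, 18.9) were also within it over all cells. RARRES1 of the retinoic acid list stood at 908 CPM against 174 CPM, and DUSP4 of the FGF list had 1.86. Inside clusters A to G the FGF and GDNF median was below the random range in 5 of 7 and above it in 1. The BMP and TGF-beta median was above the range in 4 of 7 and below it in 1.

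**Figure D4:**
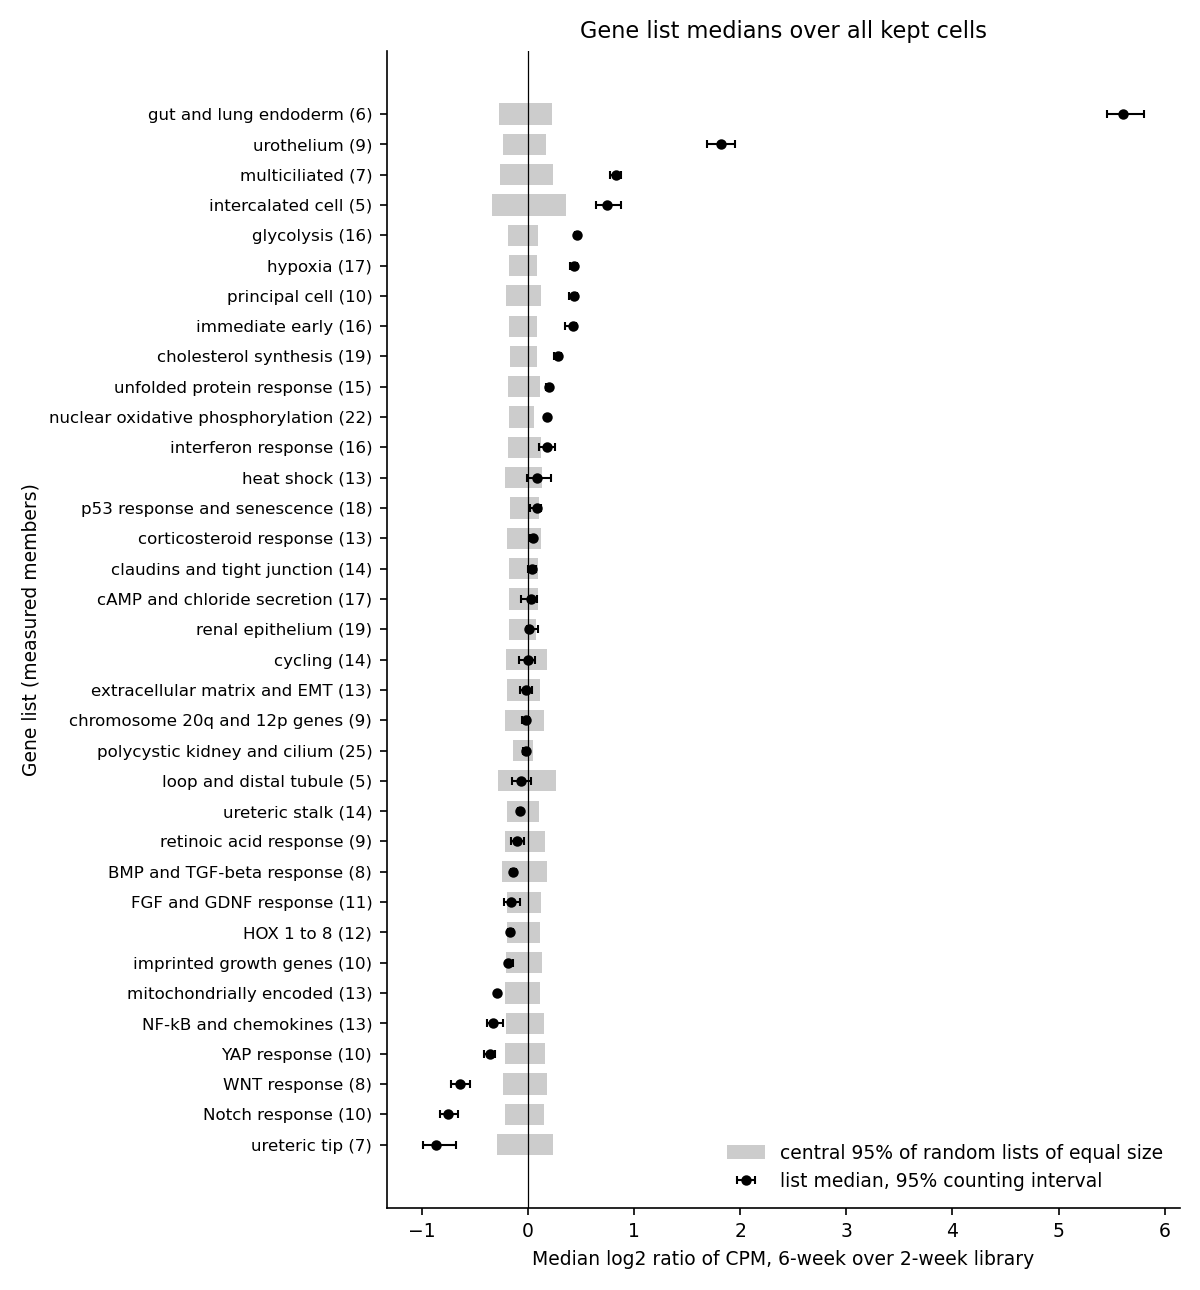
Median log2 ratio of CPM (6-week over 2-week library, all kept cells) of each fixed gene list with at least 5 measured members, with its 95% counting interval (points, lines) and the central 95% of random lists (grey bars). Principal cell, urothelium, multiciliated, intercalated cell and endoderm lists lie above the grey range, and ureteric tip, Notch, WNT, YAP and NF-kB lists below it.

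The fifth question concerned genes of cystic kidney disease and of proliferation, since the series concerns cyst formation. PKD1 and PKD2, mutated in autosomal dominant polycystic kidney disease, stood at 24.1 CPM against 29.9 CPM (log2 ratio −0.32, −0.40 to −0.23) and 68.4 CPM against 79.4 CPM (−0.22, −0.27 to −0.16). PKHD1, the recessive disease gene, stood at 310 CPM against 279 CPM (0.15, 0.12 to 0.18). None of the 25 measured polycystic kidney and cilium genes differed 2-fold, and their median of −0.02 (percentile 71.7) turned to 0.04 under edgeR's scaling and 0.02 under DESeq2's. The chloride channel gene CFTR was low in both, at 2.29 and 3.25 CPM (−0.51), and the cAMP and chloride secretion list had a median of 0.03 (percentile 86.4), with ANO1 at −1.72 and PDE3A at 3.21. PKD1 lies on chromosome 16 from 2088710 to 2135898, PKD2 on chromosome 4 from 88007668 to 88077777, and PKHD1 on chromosome 6 from 51615300 to 52087625.

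Cycling genes were low in both libraries, with MKI67 at 1.08 CPM in the 6-week and 1.54 CPM in the 2-week library and TOP2A at 7.84 and 5.79 CPM. The cycling list had a median of 0.01 (percentile 66.3) with 0 of 14 members differing 2-fold. Cells with UMIs of at least 5 cycling genes after thinning were 0.519% (0.291 to 0.855; 15 of 2889) of the 6-week and 0.861% (0.578 to 1.23; 29 of 3367) of the 2-week library, and 21.002% and 16.3% without thinning, in the opposite order. The endoderm-like cluster 10, all from the 6-week library, held 12 of those 15 6-week cells (12 of 42, or 28.6%, 15.7 to 44.6). The values over all cells therefore do not describe the renal epithelium alone. In cluster 1 such cells were 0 of 536 in the 6-week and 9 of 557 in the 2-week library. Without thinning they were 27.8% and 21.02% there, again in the opposite order.

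Within the urothelium-like class, the last comparison, multiciliated genes were higher and S100A9 and CRABP2 lower in the 6-week library. The class was cluster 3 of the clustering on all variable genes, with 139 2-week (3.95%, 3.33 to 4.65) and 681 6-week cells (22.6%, 21.1 to 24.1), and it contained all 61 cells of the multiciliated-like cluster I, 59 of them from the 6-week library. In cluster F, which holds none of those cells, C20orf85 stood at 1.57 CPM over both libraries and RSPH1 at 12.6 CPM against 9.93 CPM. The dynein gene DNAH12 stood at 109 CPM against 8.20 CPM, C20orf85 at 182 CPM against 25.7 CPM, CRIP1 at 380 CPM against 50.05 CPM and RSPH1, a ciliary radial spoke gene, at 109 CPM against 29.3 CPM, and the multiciliated list had a median of 1.93 over 11 members. S100A9, a calprotectin subunit gene, stood at 207 CPM against 685 CPM and CRABP2 at 33.8 CPM against 100.1 CPM, while SAA1 (18.6 CPM against 159 CPM) and SAA2 (24.3 CPM against 123 CPM) are near-identical copies and uncertain one by one. Of 7000 genes with a mean of at least 20 CPM there, 130 were at least 2-fold higher and 61 lower, and the NF-kB and chemokine list had a median of −0.68. The count of higher genes was far lower at resolution 1.0, where the multiciliated-like cells formed a class of their own.

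Cluster F, the urothelium-like cluster of the clustering without the 2-fold genes, gave other leading genes. PVALB stood at 102 CPM against 15.9 CPM, PLAAT3 at 344 CPM against 74.2 CPM, the carbonic anhydrase gene CA9 at 97.7 CPM against 27.2 CPM and ASS1, of arginine synthesis, at 137 CPM against 44.4 CPM. Lower were CXCL8 (11.7 CPM against 156 CPM), GADD45A (31.7 CPM against 331 CPM), HJV with 2 UMIs against 185 CPM (log2 ratio −10.40, −13.45 to −8.54), and KRTAP2-3, which had 0 UMIs and was at least 504-fold lower against the floor of 3 UMIs in the 6-week library. Of its 2-week cells, 57 of 178 (32.0%) belonged to cluster 9, which was led by KRT17 and RUNX2, against 7 of 531 (1.32%) of its 6-week cells. Among 6357 genes, 87 were higher and 127 lower.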

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

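All tests below were chosen only after the results were seen, except the UMI depth of SST-positive cells in clusters 6 and 7 and the ratio of genes longer than 200 kb. A BMP and TGF-beta response median of −0.51 (8 members, percentile 0.03) in the urothelium-like cluster F stood against 0.23 (percentile 99.2) in cluster A, opposite directions whose difference was not tested; in the urothelium-like cluster 3 of the other clustering the median was −0.14 (percentile 5.41). The unfolded protein response list likewise had −0.17 (15 members, percentile 1.505) in cluster F and 0.11 (percentile 97.6) in cluster A, also not tested, and −0.09 (percentile 11.7) in cluster 3. Cluster F did not compare like with like, since 32.0% of its 2-week and 1.32% of its 6-week cells belonged to cluster 9. Among the 678 barcodes of the 6-week library that the filter left out, with a median of 1142 UMIs, APOA2 was found in 1.77% (0.918 to 3.07), against 0 of 863 left-out barcodes of the 2-week library, where the interval allows a share of up to 0.4265%. UPK2 was found in 3.39% of the left-out 6-week barcodes and in 1.04% (9 of 863) of the 2-week ones.

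The endoderm-like cells, 44 in the clustering on all variable genes, came from the 6-week library alone. Doublets with AQP2-rich cells were argued against by AQP2, which stood at 4.48% (3.51 to 5.63) of its level in clusters 1, 4, 6 and 7 of that library, where at least 20% had been set for doublets. Undifferentiated pluripotent cells were argued against by POU5F1, at 0.633 CPM (0.016 to 3.53) in these cells and 4.77 CPM in the other 6-week cells, although SALL4 (45.0 CPM) and SOX2 (36.1 CPM), which such cells also express, were higher in them than elsewhere. Cells of another culture mixed into the library cannot be told apart from cells that arose in the longer culture, because 1 cell line and 1 library per culture time give no marker of origin for the 44 cells. Growth of an endoderm-like side population in the longer UBTC culture stays open and was not tested.

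TFF3 and SST, high in clusters 3 and 8, were also higher in the 6-week library within AQP2-rich clusters, except SST in cluster 1 (log2 ratio −1.31). Free RNA as the whole source of SST in cluster 7 was argued against by the TFF3 to SST ratio, 0.299 (0.279 to 0.321) there and 2.66 in the whole library. The ratio in cluster 7 also lay below both cluster 3 (8.15) and cluster 8 (1.09), which argues against doublets with an average mix of those cells. It cannot exclude a few doublets with single cells richer in SST, since the ratios of clusters 3 and 8 are sums over many cells. For TFF3 and SST in clusters 6 and 7 doublets stay open, since cells with at least 3 thinned SST UMIs had 1.33 times (1.02 to 1.77) the median UMIs of cells with none, between the bounds set. As a source of TFF3 in clusters 1, 2, 4, 6 and 7, free RNA cannot be told apart from expression, since no ratio lay above that of the library: the highest was 2.39 (2.12 to 2.70) in cluster 1, and those of clusters 2, 4 and 6 were 2.10, 1.75 and 1.66. For SST, free RNA stays open as well in clusters 2 and 4. In cluster 6 the interval (1.58 to 1.74) fell narrowly below the bound set for SST in cluster 7, but no bound had been set for cluster 6. A higher TFF3 and SST output of AQP2-rich cells with culture time may contribute and stays a hypothesis.

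The 274 genes at least 2-fold lower in the 6-week library, DCLK1, PNOC and SEMA3D among them, could reflect a different mix of cells, a lower share of nuclear RNA, the library preparation or the culture time. Their median log2 ratio was −1.33 within cluster A and −1.29 within cluster B, both made without these genes. These values cannot decide on a different mix, since 19.8% and 59.6% of their 2-week cells came from cluster 5, which held 9 6-week cells. In B, 87.9% of the 6-week cells came from cluster 4. On all variable genes, where cluster 5 stood apart, the medians were −1.20 in cluster 1, −0.81 in 6, −0.55 in 4 and −0.53 in 7. They argue against a mix of those clusters as the whole cause, but a mix may explain part. A different mix inside those clusters was not tested, and the genes had been chosen over these same cells. Nuclear RNA stays open: the median over 1170 genes longer than 200 kb was −0.11, between the bounds of −0.1 and −0.3 set before, and 7.01% of these against 2.22% of all genes were lower, whereas 4.36% against 2.88% were 2-fold higher and MALAT1, a nuclear RNA examined afterwards, was at −0.0093 (−0.0131 to −0.0055), which go against it. With 1 library per culture time, a difference between library preparations cannot be told apart from the culture time. A lower activity of these genes after longer UBTC culture stays open and untested.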

How the results depend on the processing

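The alternatives chosen only after the results were seen were those without the 5% of cells with the most UMIs, without the endoderm-like cluster, of clusters 1, 4, 5, 6 and 7 alone, and within the lettered clusters. No paired analysis was possible because each culture time had 1 library, and for the same reason no replicate could be left out. Keeping doublet calls in changed nothing, since none had been removed, and says nothing about stability. Of the 35 list medians, 18 lay outside the central 95% of random lists over all cells; under 14 alternatives (479 values for all 35) 4 of the 18 were reversed, each within clusters 1, 4, 5, 6 and 7 alone, which leaves out the urothelium-like, SST-led and endoderm-like cells: hypoxia −0.25, glycolysis −0.13, cholesterol synthesis −0.22 and interferon response −0.21. Of the lists inside the random range, 15 also changed sign at least once (38 values), as for BMP and TGF-beta response within those clusters (0.19) and imprinted genes with no CPM minimum and 1 UMI added (0.18). For lists apart from the principal cell, tip and urothelium lists, 282 values stayed within the counting interval and 154 moved beyond it, and these counts include the 38 sign changes. The principal cell median stayed above 0 at 0.39 (stricter filter), 0.49 (edgeR), 0.48 (DESeq2), 0.31 (at least 20 CPM), 0.51 (mean of each cell's CPM), 0.48 (thinned), 0.50 (top 5% left out) and 0.76 (clusters 1, 4, 5, 6 and 7), and the tip median below 0 at −0.52 (thinned) and −0.28 (those clusters); the causes were not tested. Genes at least 2-fold higher and lower numbered 2511 and 3607 with no CPM minimum and 1 UMI added, 2 choices changed at once whose effects were not separated, and 131 and 98 at 20 CPM, which removes genes; in clusters 1, 4, 5, 6 and 7 there were 112 higher.

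Shares of AQP2-positive cells in the 2-week and 6-week libraries were 78.2% and 66.7% unthinned, 44.3% and 39.8% at 1500 UMIs, and 39.1% and 38.2% for at least 2 UMIs, levels that depend on depth or threshold, and 58.1% and 48.5% under the stricter filter. In each of these settings the 2-week share was the higher. Shares of cells high for cycling genes were 16.3% and 21.002% unthinned, 0.371% and 0.267% at 1500 UMIs and 0.0594% and 0.0346% for at least 2 UMIs, so their order depends on depth. The urothelium-like share of the 2-week library was 5.06% without the 2-fold genes and 5.56% under the stricter filter, and of the 6-week library 17.6% without the 2-fold genes and 18.5% at resolution 1.0. Within that class the higher genes numbered 438 at 5 CPM, 201 under the stricter filter and 30 at resolution 1.0, and the lower genes 182 at 5 CPM, 112 under the stricter filter and 127 without the 2-fold genes; the cause was not tested beyond the CPM minimum. No urothelium-like cluster was named at resolution 0.3, without cycling genes, with each library alone or without the top 5% of cells, so these gave no value. Genes under the 5 CPM minimum and types under 0.0853% or 0.0995% of cells lay beyond the depth.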

Other observations

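The test in this part was chosen before its result was seen. Most lists of other lineages had few measured members. Of the pluripotency list, L1TD1 stood at 3.47 CPM in the 6-week and 21.4 CPM in the 2-week library (log2 ratio −2.62), SALL4 at 7.52 and 16.2 CPM (−1.11) and LIN28B at 18.6 and 32.5 CPM (−0.81), and L1TD1 was lower in 6 of the 6 lettered clusters where it was measured. TUBB3, the measured member of the neural list, had −1.63, and the fibrillar collagen gene COL1A2, of the stroma list, −1.46. Podocyte (PODXL at 5.70 and 7.21 CPM), proximal tubule (CUBN at 9.19 and 10.0 CPM), nephron progenitor (CRABP2 at 27.7 and 30.8 CPM), muscle (TNNT1 at 26.8 and 11.6 CPM) and squamous (KRT17 at 91.3 and 78.8 CPM) genes had fewer than 5 measured members each, and the endothelial and the blood and immune lists had 0. The loop and distal tubule list had a median of −0.07, with the calcium-binding gene PVALB at 2.39 and TMEM52B at 2.60.

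Over all cells, patterning and growth lists with at least 5 measured members lay within the range of random lists. HOX genes 1 to 8 had a median of −0.16 (percentile 5.85, 10 of 12 below 0). HOXB9, of a separate HOX list with 3 measured members and so no percentile, had −0.85. Imprinted genes had a median of −0.18 (percentile 5.28, 5 above and 5 below 0), with CDKN1C at −1.43, IGF2 at −0.63 and GNAS at 383 CPM against 319 CPM. Inside clusters A to G their median was below the random range in 4 of 7 and above it in 2. The extracellular matrix list had −0.02 over all cells and turned to 0.04 under edgeR's and 0.02 under DESeq2's scaling, with MMP7 at 297 CPM against 163 CPM, VIM at −0.75 and CDH2 at −1.02. Claudin and tight junction genes had a median of 0.04 (percentile 90.6) and corticosteroid response genes 0.05 (percentile 90.0), with MT2A, whose counts may be shared with other metallothionein genes, at 146 CPM against 92.0 CPM.

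Genes often gained with chromosomes 20q and 12p in cultured stem cells had a median of −0.02 (percentile 65.2), with CCND2 at −1.18, and this turned to 0.04 under edgeR's scaling. The hypothesis that most cells of the 6-week library had gained or lost a whole autosome relative to the 2-week library was tested in cluster A. This cluster held 20.7% of the 6-week cells. The autosome farthest from 0 was chromosome 18, with a median log2 ratio of −0.071 over 176 genes (quartiles −0.28 and 0.06) after the median of all genes was subtracted. At least 0.3 either way had been set for a gain or loss and within 0.2 for none, so the value argues against it for the cells of cluster A. A gain or loss in a small part of the cells, outside cluster A or shared by both libraries could not be seen this way.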
